A study of Mus musculus with 8 samples.

How the data were processed

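RNA from exosomes of the murine mast cell line MC/9 and from the cells themselves was measured on 8 Affymetrix Mouse430_2 arrays, 4 per group. Per the labels' protocols, exosomes were taken from the culture supernatant by spinning at 500 g for 10 min and 23000 g for 20 min, filtering through 0.22 µm and pelleting at 145000 g for 70 min. Total RNA was extracted with Trizol, and biotinylated cRNA was made from 5 µg for each array. The medium held fetal bovine serum and a rat T cell culture supplement, per the labels' protocols, so RNA of other sources can be present in the exosome pellet.

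The values used are the intensity values per probe set that the authors deposited, on a linear scale. They are signals from GCOS, the Affymetrix software, per the submitters' processing notes, with no version given there. The way probe intensities were summarised into probe sets and the background treatment are not given in the sources used here. The deposited intensity values have a 2% trimmed mean of 100 on each array, which is a global scaling. It raises all signals of an array whose RNA gives little signal, background included. The median of the whole table is 41.8.

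The experiment files of the arrays, the other files deposited by the authors, hold settings of the instrument and no expression values. By the hybridisation date in the file headers, the arrays fall into 2 batches. Replicates 1 and 2 of both groups are in batch 1, and replicates 3 and 4 of both groups are in batch 2. Batch values are given beside the pooled ones. The labels call the samples biological replicates, but nothing used here says that they came from separate cultures, so p-values may measure only the spread between these samples.

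Of 45101 probe sets, 64 are Affymetrix controls. Of the rest, 34945 have 1 gene symbol in the platform annotation used here, 932 have several and 9160 have none. Only those with 1 symbol were named. Of them, 34741 matched a gene of the mouse RefSeq gene table (assembly GRCm38.p6, used for names only) by gene ID, and 0 symbols changed. They name 18193 genes. Gapdh and Cd63, which were to be given in any case, have no probe set with a single symbol here, so Gapdh is given through its control probe sets and Cd63 is not analysed here.

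The detection floor of an array is the 95th percentile of the signals of 147 background-list probe sets on it. These are olfactory, vomeronasal and taste receptors, keratin-associated proteins and beta-defensins. About 5% of unexpressed probe sets pass such a floor by construction. A probe set was tested if it was above the floor on at least 3 of the 4 arrays of a group, with control probe sets left out, which kept 20182. Values are log2(signal + 4), with pseudocount 4 because the table's median is under 50. Differences are on this scale, which understates changes of dim probe sets. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a probe set was above the floor on no array of the lower group, a fold is given as a bound: the geometric mean of the higher group over the geometric mean, across the arrays of the other group, of the higher of the array's floor and the probe set's signal ("at least N-fold"). Bounds are on the deposited scaling. No probe set's level was compared with another's in these tests. Single values per array were compared with two-sided exact permutation tests over 70 assignments.

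Before the data were examined, 28 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The rule names the 10 genes with the largest rises and the 10 with the largest falls among genes above the floor on all arrays of the higher group, past the threshold and with no overlap between groups. It also names up to 2 rises and 2 falls within each list, 12 genes in any case and the 5 exosome-only probe sets with the highest signal. One probe set stands for a gene, the one with the highest mean over all 8 arrays. That mean includes the exosome arrays, so the choice can favour a probe set that is bright there. This bears on the counts of genes that rose or were above the floor in exosomes. The retroviral list was built from symbol patterns, and its single tested member, Etnk1, is not retroviral. Lists with at least 5 tested genes (18) were compared with the other genes by camera with a preset correlation of 0.01, with an estimated correlation and with fry. The number of genes of a list detected in exosomes was compared with 10000 random sets matched on cell signal, a test chosen after the data were seen.

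On simulated data with changes added to 200 of the 20182 probe sets, the test recovered 4% of changes of 1 on the log2 scale. It recovered 16% of changes of 2, 70% of changes of 4 and 92% of changes of 6. Of its 111 calls, 20 were among the 19982 unchanged probe sets, a larger share than the threshold for adjusted p-values. Far more probe sets were called in the data, 11175 of 20182, so these rates may not carry over to the data. In 50 simulations camera called 50 shifted lists of 30 genes and 2 unshifted ones. The matched test called 2 of 40 random lists and 40 of 40 lists with 10 detected genes added.

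Alternatives were quantile normalization, scaling to the probe sets above the floor on all 8 arrays, to the hybridisation controls or, chosen after the data were seen, to the poly-A controls, subtraction of the background median, pseudocounts of 1 and 64, other floors and filters, signals set to the floor, no variance trend, array weights, a batch or replicate block, each batch alone and leaving out each array. Scripts also used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. A comparison by transcript length was left out because no transcript lengths were used here.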

Results

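Exosomes are small vesicles that cells release into their medium. The question was which transcripts the exosomes of a mast cell line carry and how their RNA compares with that of the parent cells. RNA was extracted from exosomes shed by MC/9, a murine mast cell line, and from the MC/9 cells themselves, and each extract was hybridised to an Affymetrix mouse whole-transcriptome array. There were 4 exosome arrays and 4 cell arrays, which the labels call biological replicates. The arrays fell into 2 hybridisation batches, each with 2 exosome and 2 cell arrays, and the number of arrays limits the precision of every value. Signals correlated across probe sets with Pearson's r of 0.94 to 0.97 between cell arrays, 0.40 to 0.51 between exosome arrays and 0.11 to 0.19 between the groups. These correlations run across probe sets, which are not independent replicates, and no array repeated another.

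Far fewer transcripts were measurable in exosomes than in cells. On average 2704 ± 950 probe sets (SD, n = 4) lay above the detection floor on an exosome array, or 6.0% of the array, against 21371 ± 992 (SD, n = 4), or 47.5%, on a cell array. About 5% of unexpressed probe sets pass this floor by construction, and the exosome arrays ranged from 3.28% to 8.42%. Most probe sets above the floor on a single exosome array may thus be background. With a floor at the 99th percentile the means were 501 in exosomes and 18080.5 in cells. The ranges were 1478 to 3793 for exosomes and 20278 to 22636 for cells, and the difference exceeded the spread between replicates (two-sided exact permutation test, p = 0.029, the smallest that 4 against 4 arrays can give). It was -18848 probe sets within batch 1 and -18486 within batch 2. All 4 exosome arrays shared 640 probe sets above the floor. Of these, 337 had a single gene symbol and stood for 286 genes, while 124 had several symbols and 179 had none.

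**Figure D1:**
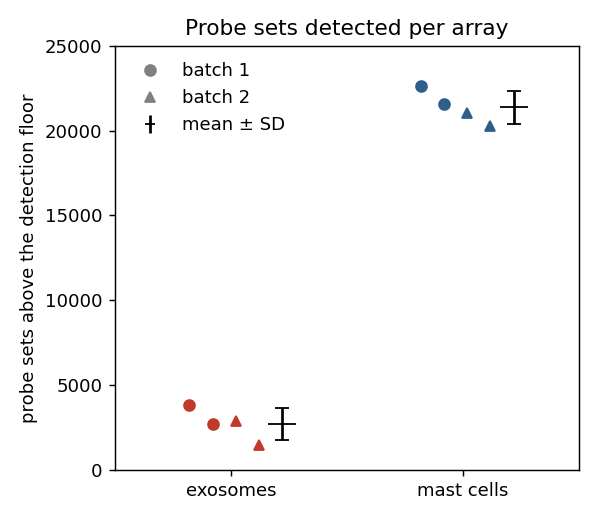
Number of probe sets above the detection floor on each array (vertical axis), by group, with circles for batch 1, triangles for batch 2 and the group mean ± SD (n = 4). The 4 exosome arrays lie between 1478 and 3793 and the 4 cell arrays between 20278 and 22636.

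The transcripts measured on all exosome arrays were mostly also measured in the cells. Of the 640 probe sets, 426 (203 genes) were above the floor on all 4 cell arrays and 117 (37 genes) on none of them. Those 117 held few named genes: 59.0% had no gene symbol, against 20.3% of all probe sets. The 5 with the highest exosome signal were all unnamed, and the highest had a signal of 26649 ± 2450 in exosomes and 2.01 ± 1.09 in cells (SD, n = 4), at least 2035-fold higher in exosomes on the deposited scaling. That bound holds for this scaling alone. The fitted log2 difference of that probe set went from 12.1 to 8.65 with arrays scaled to the hybridisation controls. Conversely, 14773 probe sets (8338 genes) were above the floor on all cell arrays and on no exosome array. For 10851 of them (73.5%) the cell signal itself did not exceed the exosome floor on the deposited scaling. A deposited signal like that of the cells would thus not have passed this floor. The scaling raises the floor of the exosome arrays with their other signals, so this count holds for that scaling alone and does not compare transcript levels. A floor at the 99th percentile of the background list left 50 probe sets in exosomes alone, and within batches the number was 388 and 375.

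Detection in exosomes was concentrated among the probe sets with the brightest cell signals. Among probe sets above the floor on all cell arrays, 13.3% of those in decile 10 of cell signal, the brightest, were above the floor on all exosome arrays, against 0.610% to 1.88% in deciles 1 to 9. The median cell signal was 1656 for the 426 probe sets measured throughout both groups and 124 for the 14773 measured in cells alone. These values rank different probe sets by signal, which also depends on their probes, so they do not rank transcript levels.

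The arrays of the groups also differed in background and control signals, which bears on every level below. The deposited scaling gives each array a 2% trimmed mean of 100. On this scale the bacterial hybridisation controls, added to each hybridisation, were higher on exosome arrays by 4.59 on the log2 scale (4.50 in batch 1 and 4.67 in batch 2; exact permutation test, p = 0.029). The poly-A controls were higher by 3.51 (3.20 in batch 1 and 3.81 in batch 2; exact permutation test, p = 0.029). The median signal of the background list, which holds sensory receptor and keratin-associated genes, was 71.2 ± 4.41 on exosome arrays and 2.43 ± 0.457 on cell arrays (SD, n = 4; exact permutation test, p = 0.029), a difference that shrank to 0.30 on the log2 scale with arrays scaled to the hybridisation controls (exact permutation test, p = 0.51). The detection floor was correspondingly 284 ± 40.3 and 13.2 ± 2.56 (SD, n = 4).

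**Figure D2:**
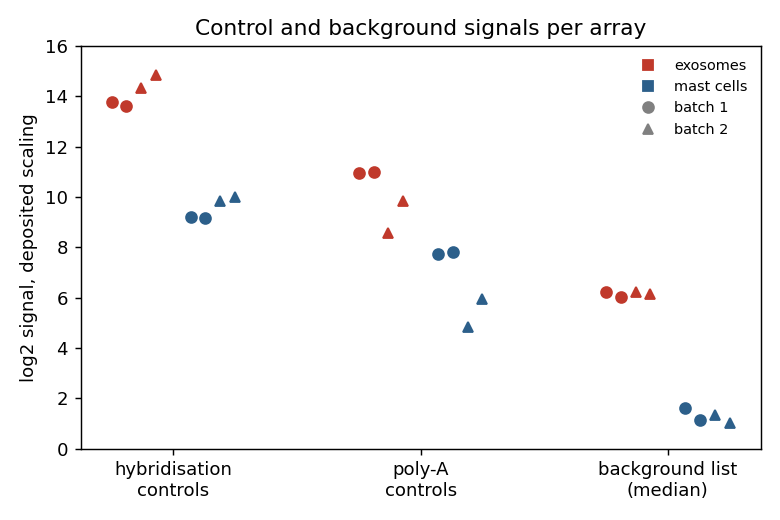
Log2 signal per array (vertical axis, deposited scaling) of the hybridisation controls, the poly-A controls and the background list's median, in red for exosomes and blue for cells, with circles for batch 1 and triangles for batch 2. In each of these sets the 4 exosome arrays lie above all 4 cell arrays.

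Transcripts that mark mast cells were abundant in the cells and low in exosomes. Kit, the stem cell factor receptor, had a signal of 2129 ± 813 in cells and 99 ± 104 in exosomes (SD, n = 4), was above the floor on no exosome array and was at least 7.12-fold lower there (limma, adjusted p = 0.000514). The next genes were above the floor on 1 or 2 exosome arrays, so their falls on the log2 scale are given with signals under the floor set to the floor. Cpa3, mast cell carboxypeptidase, had 8449 ± 856 in cells and 196 ± 97.2 in exosomes (SD, n = 4), above the floor on 1 array, and fell by 4.81 (limma, adjusted p = 1.15e-06 for the signals as deposited). Fcer1a, the alpha chain of the IgE receptor, fell by 4.75 and Ms4a2, the beta chain, fell by 4.01 (limma, adjusted p = 1.25e-06 and 2.74e-06 as deposited) and were above the floor on 2 exosome arrays and 1 exosome array. Srgn, the granule proteoglycan serglycin, fell by 4.59 and was above the floor on 1 exosome array. Hdc, which makes histamine, was above the floor on no exosome array and was at least 4.50-fold lower. Of the 26 tested genes of the mast cell list, 24 fell, none rose and 2 did not pass, with 25 falling when adjusted over the list alone. None was above the floor on all exosome arrays.

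Of the lists tested, ribosomal protein transcripts were the best represented in exosomes, although most were lower there than in cells. Of 45 tested genes, 25 were above the floor on all exosome arrays, 40 fell, 3 rose and 2 did not pass, and the counts were the same when adjusted over the list alone. Rps29 had a signal of 4355 ± 1203 in exosomes and 8639 ± 1258 in cells (SD, n = 4), a fall by 1.02 on the log2 scale that became 0.02 in the other direction with arrays scaled to the probe sets above the floor on all 8 arrays. Rps9 and Rpl8 were above the floor on 1 and 2 exosome arrays and Rps9 fell by 4.23 and Rpl8 fell by 3.71 with signals under the floor set to the floor. The 3 that rose, Rpl27a, Rpl39 and Rps27, did so on probe sets that read 113 ± 27.0, 59.7 ± 28.7 and 78.4 ± 23.6 in cells (SD, n = 4) and were above the floor on 3, 3 and 2 exosome arrays, and they were named after their values were seen.

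Transcripts of energy metabolism and protein turnover were lower in exosomes. For nuclear-encoded oxidative phosphorylation, 70 of 74 tested genes fell and 2 rose, with the same counts when adjusted over the list alone, and 7 were above the floor on all exosome arrays. Cox5b, a subunit of cytochrome c oxidase, was one of these, with 859 ± 316 in exosomes and 3322 ± 602 in cells (SD, n = 4), a fall by 2.00 on the log2 scale. That fall became 0.97 with arrays scaled to the probe sets above the floor on all 8 arrays, and with quantile normalization the difference was -0.02 and did not pass (limma, adjusted p = 0.95, against 1.32e-09 to 0.0021 with the other scalings). Cox8c rose by 3.95 but turned to -0.43 with arrays scaled to the hybridisation controls. Of the proteasome genes, 36 of 37 fell and none rose, also when adjusted over the list alone, with 3 above the floor on all exosome arrays, and Psmc3 fell at least 3.73-fold. Among 16 glycolysis genes 12 fell and 1 rose, also when adjusted over the list alone, and 1 was above the floor on all exosome arrays. Slc2a1, a glucose transporter, was at least 5.29-fold lower. Mitochondrial ribosomal proteins gave 58 that fell and 1 that rose of 76 (60 and 1 adjusted over the list alone), with 0 above the floor on all exosome arrays. ND5, the single mitochondrially encoded gene named on the array, had 4494 ± 2167 in cells and 119 ± 26.4 in exosomes (SD, n = 4), at least 14.5-fold lower.

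Translation, secretion and cell-structure transcripts followed the same direction. Of the translation factors, 41 of 56 fell and 1 rose (44 and 1 adjusted over the list alone), with 4 above the floor on all exosome arrays. The 1 that rose was Eif2ak2, a kinase that inhibits translation, and its change of 2.82 turned negative with arrays scaled to the hybridisation or the poly-A controls. Of the endoplasmic reticulum chaperones, 18 of 23 fell and 1 rose (20 and 1 adjusted over the list alone), with 0 above the floor on all exosome arrays, and Hspa5, the chaperone BiP, was at least 13.3-fold lower. Cytoskeletal genes gave 20 of 21 that fell and 1 that rose, also when adjusted over the list alone, with 3 above the floor on all exosome arrays, and Actb fell by 4.04 from 6366 ± 249 in cells to 402 ± 144 in exosomes (SD, n = 4), while its single other tested probe set went the other way. Of the cell cycle genes, 23 of 29 fell and none rose (24 adjusted over the list alone), Ccnd2 alone was above the floor on all exosome arrays, and Cdc6, a replication licensing factor, was above the floor on no exosome array, where the mean floor of 284 lay within the range of its cell signals, 234 to 320, so no size of a fall is given.

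Genes for exosome formation were mostly lower in exosomes as well, while those for small RNA handling were less clearly so. Of 29 tested genes for exosome and endosome sorting, 21 fell and 2 rose, also when adjusted over the list alone. Hspa8, the heat shock cognate protein used as an exosome marker, fell by 3.08 and was above the floor on all exosome arrays at 828 ± 238 against 6854 ± 837 in cells (SD, n = 4). Cd151, a tetraspanin, rose by 3.49, but turned to -0.92 with arrays scaled to the hybridisation controls, and its 4 other probe sets went the other way. Cd81, another tetraspanin, lay under the floor on all 8 arrays. Of 24 genes for small RNA machinery and RNA-binding proteins, 14 fell and 2 rose, also when adjusted over the list alone, which became 7 and 4 with arrays scaled to the probe sets above the floor on all 8 arrays, with Tnrc6c and Ybx1 above the floor on all exosome arrays. As a set this list did not pass against the other genes (camera with the preset correlation, adjusted p = 0.33). Fmr1, an RNA-binding protein, was at least 1.98-fold lower.

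Regulatory and noncoding transcripts were mixed. Zinc finger transcription factors split into 46 that rose and 49 that fell of 242 tested (43 and 42 adjusted over the list alone), with 4 above the floor on all exosome arrays. With the deposited scaling 34 rose and 33 fell within batch 1 and 59 and 33 within batch 2. With the other scalings the split was uneven: 20 rose and 102 fell with quantile normalization, 86 and 21 with arrays scaled to the probe sets above the floor on all 8 arrays, 17 and 108 after subtracting the background median, 2 and 233 with arrays scaled to the hybridisation controls and 2 and 190 with arrays scaled to the poly-A controls. Zfp982 rose by 5.61 and passed under each of the 5 other scalings, and Zfp330 was at least 1.46-fold lower. Of the snoRNA host transcripts, 7 of 9 fell and none rose, also when adjusted over the list alone, and Gas5 was at least 9.65-fold lower. Among nuclear long noncoding RNAs, 2 rose and 1 fell of 6, also when adjusted over the list alone, with neither rise above the floor on all exosome arrays and 1 above it on none, and Neat1 was at least 5.58-fold lower. Xist was above the floor on 2 cell arrays and no exosome array and was not tested. Histone genes gave 2 that rose and 5 that fell of 13, also when adjusted over the list alone, with neither rise above the floor on all exosome arrays and 1 above it on none, and H2az2 was at least 6.88-fold lower, while its single other tested probe set went the other way. Cytokine and chemokine genes gave 3 and 5 of 15, also when adjusted over the list alone, with 2 of the 3 rises above the floor on no exosome array and Ccl2 at least 6.28-fold lower. Immediate early and stress genes gave 0 that rose and 5 that fell of 13 (2 and 6 adjusted over the list alone), with Ier3 at least 7.78-fold lower. The single tested member of the retroviral list was Etnk1, an ethanolamine kinase that is not retroviral, and it was at least 9.37-fold lower.

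**Figure D3:**
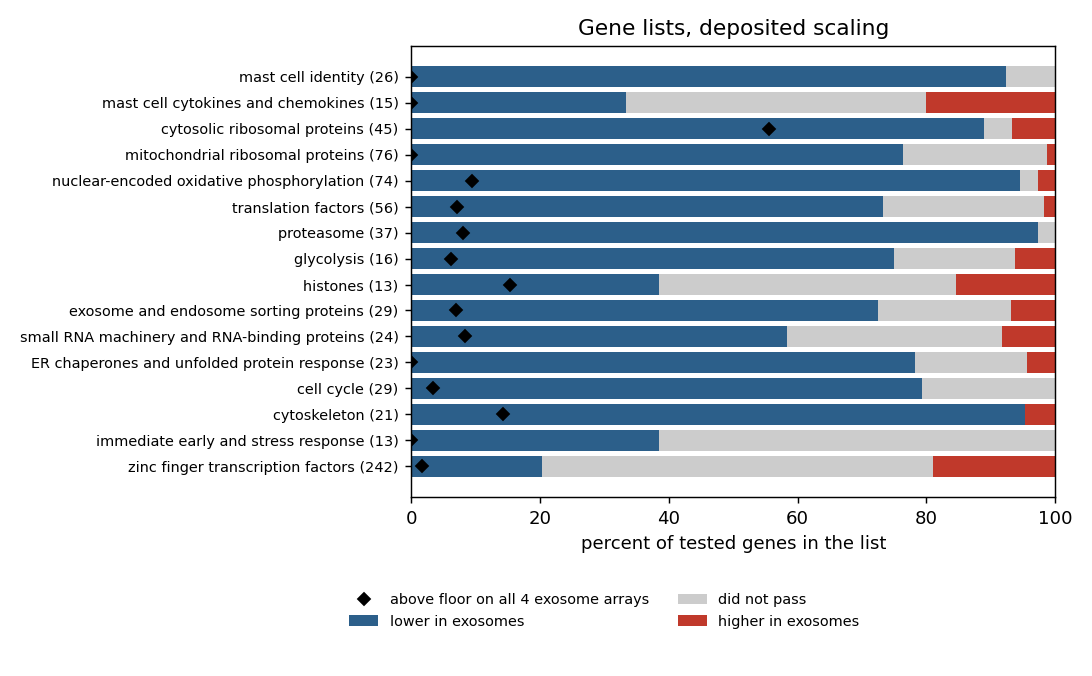
Share of the tested genes of each list (horizontal axis, percent; number tested in brackets; smaller lists not drawn) that were lower in exosomes (blue), did not pass (grey) or were higher (red) with the deposited scaling, and the share above the floor on all 4 exosome arrays (diamonds). Of 45 ribosomal protein genes 25 were above the floor on all exosome arrays, and of 26 mast cell genes none was.

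Tested as sets against the other genes with limma's camera (18 lists, preset correlation), 11 lists shifted lower and 1, the zinc finger genes, was called higher than the other genes. That call rests mostly on signals under the floor, since 202 of its 242 genes were above the floor on no exosome array, and it was lost with quantile normalization. The calls of the translation factor, glycolysis, exosome sorting and cytoskeleton lists were lost there too, and that of glycolysis with arrays scaled to the hybridisation controls. Signals under the floor weigh on lists called lower too. Above it on no exosome array were 21 of 23 endoplasmic reticulum, 64 of 76 mitochondrial ribosomal and 29 of 37 proteasome genes. Shares were lower for the cytosolic ribosomal (4 of 45), glycolysis (6 of 16) and cytoskeleton (9 of 21) lists. Median cell signal was 328 to 6822 in the 11 lower lists and 73.5 in the zinc finger list. The set test does not separate exosome content from cell level. No list passed with an estimated correlation, where the smallest value was adjusted p = 0.061 with an estimated correlation. That value held for the mast cell, translation factor, proteasome, exosome sorting, endoplasmic reticulum and cell cycle lists. It was 0.065 for the zinc finger genes, 0.34 for the cytosolic and 0.12 for the mitochondrial ribosomal proteins, 0.11 for both oxidative phosphorylation and the cytoskeleton and 0.24 for glycolysis (adjusted p with an estimated correlation in each). For the histone and the immediate early lists the mean shift against the other genes was -0.29 and -0.02 while camera, which did not pass, gave the direction as up. By fry, which asks only whether a list's genes move one way, 16 lists were lower and 1, the nuclear long noncoding RNAs, was called higher although its mean and median log2 differences were -0.18 and -0.61 and 5 of its 6 genes were above the floor on no exosome array, while the zinc finger genes did not pass (adjusted p = 0.38). The median log2 difference was negative under all 6 scalings for each list except the nuclear long noncoding RNAs and the zinc finger genes, where it became 0.28 and 0.94 with arrays scaled to the probe sets above the floor on all 8 arrays. With that scaling 3 genes fell and 5 rose of the immediate early list, 4 and 4 of the histones, 3 and 3 of the cytokines and 30 and 4 of the mitochondrial ribosomal proteins. Of the 67 rises counted in these 18 lists, 7 were above the floor on all exosome arrays, 31 on some and 29 on none, and only 2, both of zinc finger genes, were called with arrays scaled to the hybridisation controls. Within batches 1 and 2 the mean shift was -3.09 and -3.04 for the mast cell list and -0.86 and -2.05 for the ribosomal proteins, and it changed sign between batches for the cytokine, histone and immediate early lists. Over both batches the ribosomal shift of -1.45 became -0.12 with quantile normalization.

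Single genes reached larger differences in both directions. The falls that ranked first by fitted difference among genes with a single symbol all rested on exosome signals under the floor, so that their sizes are known only as bounds, which do not follow that order. They were those of Plgrkt, a plasminogen receptor, at least 8.58-fold lower in exosomes, Serpinb1a, a protease inhibitor, at least 18.2-fold lower, and Cited2, a transcriptional coregulator, at least 8.86-fold lower. Osbpl8, Msmo1, Ncl, Oat, Ly6e and Cst3 were also among these 10, with bounds from at least 4.56-fold to at least 14.9-fold, the highest being that of Ly6e, whose single other tested probe set went the other way. Other probe sets also went the other way for Hspa5, Eif2ak2 and Fmr1 (1 of 2 each), Hspa8 (1 of 3) and Ncl, Etnk1 and Cox5b (1 of 4 each). The largest rise was that of Bzw2, with 16981 ± 3495 in exosomes and 32.6 ± 20.5 in cells (SD, n = 4), a log2 difference of 8.99 ± 0.38 (SE; limma, adjusted p = 2.79e-07), although its other tested probe set went the other way. Ntmt1, an N-terminal methyltransferase, rose by 7.87, and its other probe set also went the other way. Gm9222 rose by 7.95 and Gm3715 was at least 202-fold higher on the deposited scaling alone. With arrays scaled to the hybridisation controls the fitted log2 difference of Gm3715 went from 8.38 to 4.64. The other genes of the 10 with the largest rises were 4933438K21Rik, 9530057J20Rik, Igkv19-93, Orly and the vomeronasal receptors Vmn1r58 and Vmn1r148, which belong to the background list. The 10 falls and the 10 rises so ranked all kept their direction under the 5 other scalings.

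Across all probe sets, 11175 of 20182 tested passed limma's test at an adjusted p under 0.05, of which 3590 were higher and 7585 lower in exosomes, and 11060 of them differed at least 2-fold. The call counts were 8813 within batch 1 and 10327 within batch 2, and 11478 with the batch as a block. The split depended on the scaling: 32.1% of calls were higher with the deposited values, 13.3% with quantile normalization, 56.5% with arrays scaled to the probe sets above the floor on all 8 arrays, 12.2% after subtracting the background median, and 1.26% and 1.80% with arrays scaled to the hybridisation and the poly-A controls. The median log2 difference of all tested probe sets was -0.69, -1.66, 0.27, -2.40, -4.79 and -3.84 in that order. Of the 3590 higher calls, 369 were above the floor on all exosome arrays and 1861 on none. Higher under every one of these scalings and above the floor on all exosome arrays were 155 probe sets (45 named genes), and 107 (40 genes) so measured were lower under every one. Without regard to the floor in exosomes, 4213 probe sets (3001 genes) were lower under every one. Of the 7585 lower calls, 6493 were above the floor on no exosome array, and the bound exceeded 1 for 3848 of these, with a median of at least 1.95-fold.

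**Figure D4:**
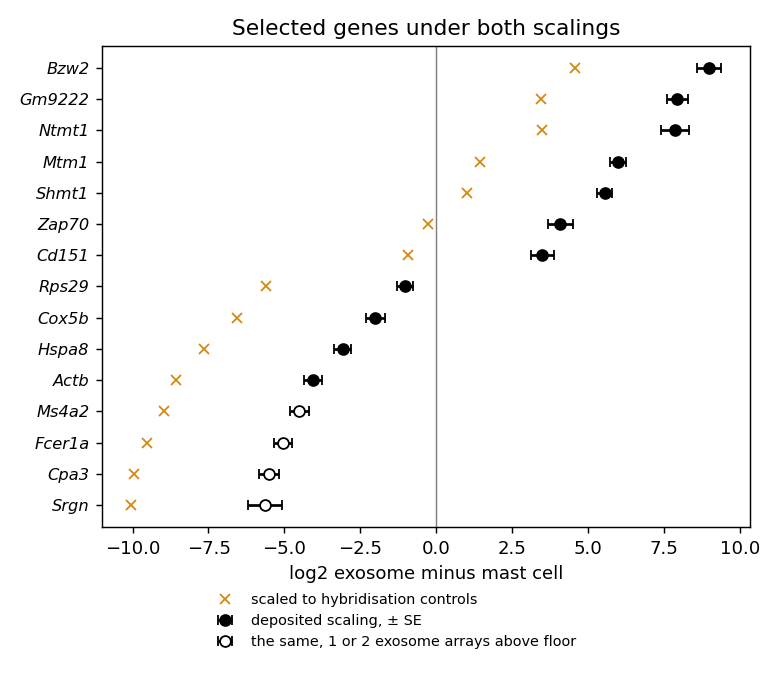
Log2 difference, exosome minus mast cell (horizontal axis), of selected named genes with the deposited scaling (circles ± SE; open circles for genes above the floor on 1 or 2 exosome arrays, whose falls rest partly on signals under the floor) and with arrays scaled to the hybridisation controls (orange crosses). Fcer1a, Cpa3 and Hspa8 are lower under both, Bzw2 is higher under both, and Zap70 and Cd151 change sign.

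Markers of other cell types were mostly not measurable in either group. No granulocyte or liver and serum protein marker was tested, and 11 genes of the other marker lists were. Zap70, a T cell kinase, rose by 4.09 and was above the floor on all exosome arrays at 524 ± 90.4 (SD, n = 4), but turned to -0.28 with arrays scaled to the hybridisation controls. The B cell marker Ighm rose and was above the floor on 1 exosome array, and of the macrophage markers 2 rose and 1 did not pass, all above the floor on no exosome array. Of 4 erythroid and platelet markers 2 rose, both above the floor on no exosome array, and 1, Itga2b, fell. Itga2b, above the floor on 2 exosome arrays, fell by 2.62 with signals under the floor set to the floor but did not pass with quantile normalization (limma, adjusted p = 0.061). Of 2 fibroblast, endothelial and epithelial markers Epcam rose, above the floor on no exosome array, and Pecam1 was at least 1.32-fold lower. In the background list 7 of 8 tested genes rose. With arrays scaled to the hybridisation controls no marker of these lists was called higher, and 2 background genes were.

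Of the 11 ratios and 18S tests that bear on RNA quality, none passed after Benjamini-Hochberg adjustment (exact permutation tests, smallest adjusted p = 0.063). The design nearly fixed this: the smallest exact p of 4 against 4 arrays, 0.029, passes only if most of the 11 tests reach it. Both Gapdh ratios, 3' to 5' and 3' to middle, and the 18S probe sets did reach it. The result therefore does not show that RNA quality was alike. The 3' to 5' signal ratio of the Gapdh control probe sets was 3.37 ± 0.781 in exosomes and 0.960 ± 0.173 in cells (SD, n = 4), a log2 difference of 1.80 (2.28 in batch 1 and 1.32 in batch 2; exact permutation test, p = 0.029, and 0.063 adjusted). The actin ratio was 5.56 ± 3.53 and 1.82 ± 0.467 (SD, n = 4), which did not pass (exact permutation test, p = 0.057), and both of its probe sets were above the floor on only 1 exosome array. The transferrin receptor and pyruvate carboxylase ratios ran the other way, by -1.35 and -2.51 on the log2 scale, and did not pass (exact permutation test, p = 0.14 and 0.086), with both probe sets above the floor on 0 exosome arrays and 2 cell arrays. The middle 18S ribosomal RNA probe set read higher in exosomes by 6.13 on the log2 scale (7.63 in batch 1 and 4.63 in batch 2; exact permutation test, p = 0.029 and 0.063 adjusted), but by 1.54 relative to the hybridisation controls (3.13 in batch 1 and -0.05 in batch 2; exact permutation test, p = 0.40). For the 3' 18S probe set the difference was 4.70, but 0.12 relative to the hybridisation controls (0.88 in batch 1 and -0.65 in batch 2; exact permutation test, p = 0.89).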

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

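The tests of the 18S pattern, of the splits of the arrays and those matched on probe set design were chosen after the results were seen. How the tests of nonspecific signal, of gene symbols, of plain probe sets and of 18S were read was also revised after their results were seen, for the reasons given with each. Of 131 groups of 4 values, 2 had an array far from the others, against 6.55 that chance gives. Cell replicate 3 had a log2 signal of 10.02 for the B1 repeat control probe set, below the other cell arrays. Exosome replicate 2 had a signal of 30322 for the unnamed exosome-only probe set with the highest signal, above the other exosome arrays. The control probe sets for the B1 and B2 repeats, short interspersed elements that the comparisons above do not use, were higher in exosomes by 5.27 and 4.06 on the log2 scale. Relative to the hybridisation controls these differences were 0.69 and -0.53 (exact permutation test, p = 0.37 and 0.11), and relative to the poly-A controls they were 1.76 and 0.55 (exact permutation test, p = 0.029 and 0.54).

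Chance alone is argued against but not excluded for the number of calls. Of the 35 splits of the 8 arrays, 1, the real one, gave as many as 11175. That is the smallest share that 35 splits can give, and the highest of the others, the split by batch included, gave 0. Each of the others mixes exosome and cell arrays within its groups, which widens the spread there, so few calls could be made. All splits were also run on the probe sets kept with the real groups. Chance is likewise argued against for probe sets seen in a single group, where 1 split of 35 gave as many as 117 in the smaller direction and the highest other gave 7.

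The 117 probe sets seen in exosomes alone, most of them unnamed, form the first pattern. A single hybridisation batch is argued against for their number: lists of 388 and 375 probe sets, made within each batch separately, shared 117 where independent lists would share 3.23 (Fisher's exact test, p = 1.13e-151), or 4.66 among the probe sets that no cell array detected (Fisher's exact test, p = 1.65e-138). The 117 are by definition the overlap of these lists, so the test bears on their number alone. It takes probe sets as independent, and signal tied to particular probes could repeat across batches too. Nonspecific signal of particular probes could not be decided. Of 105 probe sets of the marker lists that no cell array detected, 0 were above the floor on all exosome arrays, against 114 of 19345 others (Fisher's exact test, p = 1), and the background list, of which 3 of 127 were, sets the floor and cannot serve. Transcripts special to exosomes also stay open: 33.3% had a single symbol against 70.0% of other probe sets undetected in cells (Fisher's exact test, p = 4.66e-16), but a probe set unnamed here is not one without a gene, so the test written for this does not decide it.

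The ribosomal protein genes above the floor on all exosome arrays, 25 of 45, and the mast cell genes, 0 of 26, form the second pattern. Cell abundance alone is argued against for the first, where random sets matched on cell signal gave 10.3 on average (5th to 95th percentile 6 to 15). The adjusted p was 0.0036 in this random-set test of 18 lists, resting on the smallest p the draws can give. For the second they gave 4.31 (2 to 7; adjusted p = 0.031 in the same random-set test). The genes drawn for the mast cell list could include the ribosomal ones, so the 2 results are not independent and the second does not decide on cell abundance. Matched on probe set design too, the ribosomal expectation was 7.92 (4 to 12; random-set test, adjusted p = 0.0036), so probe design with abundance is argued against there but not excluded. The mast cell expectation was 2.03 (0 to 4; random-set test, adjusted p = 0.91), and the mast cell part cannot be told apart from probe design. Of 19 mast cell genes with a plain probe set 0 were above the floor against 1.25 expected (0 to 3), which did not pass either. All these draws take genes as independent, while the ribosomal genes had an estimated correlation of 0.45, so the p-values may be too small. Matched genes were the nearest in cell signal with no limit on distance, so matches of the brightest ribosomal genes may be dimmer. Probe sets shared with pseudogenes stay open for the ribosomal genes. Of 12 with a plain probe set 3 were above the floor against 0.499 expected, above the 95th percentile of 2, but this did not pass (random-set test, adjusted p = 0.15). Those 12 had a median cell signal of 261 against 6822 for all 45, so the bound set for it was a poor one. A selective content of ribosomal protein transcripts in exosomes stays open too, with transcript length and RNA degradation untested.

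The 18S signal of exosomes, which differed between batches, forms the third pattern. The middle probe set read 8622 and 10678 on the exosome arrays of batch 1 and 556 and 611 on those of batch 2. A batch effect common to both kinds of sample is argued against for the middle and the 3' probe sets, which were above the floor on all 8 arrays. Relative to the hybridisation controls their drop from batch 1 to batch 2 on the log2 scale was larger in exosomes than in cells by 3.18 (4.94 and 1.76) and 1.53 (2.95 and 1.42), where the arrays' ranges sum to 1.33 and 0.61. With each array's floor subtracted the differences were 3.74 and 2.54, where the ranges sum to 2.21 and 1.11. For the 5' probe set it stays open, since the difference of 0.90 lies within ranges that sum to 2.25 and the probe set was above the floor on 5 arrays and on neither cell array of batch 2. Differences between the exosome preparations or their labelling stay open, and no biological explanation was tested, since the design has no groups within exosomes.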

How the results depend on the processing

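Scaling to the poly-A controls, batches for detection, and control scaling of 18S were chosen after the data were seen. Where a value is said to differ between settings, the cause was not tested unless the setting itself changes the number of probe sets tested. Signal over background is the limit for exosomes, where 6.0% of probe sets exceeded the floor.

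Higher calls were 3590 and became 1539 with quantile normalization, 5723 with scaling to the probe sets above the floor on all 8 arrays, 243 with hybridisation control scaling, 294 with poly-A scaling, 1546 with the background subtracted, 26587 with no filter, 160 of the probe sets above the floor on all 8 arrays, 1711 with a floor at the 99th percentile and 13652 with signals set to the floor. Lower calls were 7585 and became 4411 with scaling to the probe sets above the floor on all 8 arrays, 19107 with hybridisation control scaling, 16057 with poly-A scaling, 217 for all 8 arrays and 4096 with signals set to the floor. Higher calls above the floor on all exosome arrays were 369 and became 157 with hybridisation control scaling, 172 with poly-A scaling, 160 for all 8 arrays and 225 with the 99th percentile floor. Calls of at least 2-fold were 11060 and became 19350 with hybridisation control scaling, 34496 with no filter and 357 for all 8 arrays. All of these kept within 1.5 times under the other settings. Leaving out 1 array gave 2851 to 3723 higher and 6691 to 7707 lower calls.

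Whether the numbers of the samples pair them could not be told: same-numbered arrays had correlations of deviations of -0.02, -0.03, -0.07 and 0.01. Exosome and cell arrays of the same batch, which share a hybridisation, also gave only -0.07 to 0.01, so the check could miss a shared culture. With the replicate block there were 3312 higher and 7420 lower calls.

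Of the 18 lists 12 passed, and 0 did with an estimated correlation, also with the replicate block and an estimated correlation, 7 with quantile normalization and 2 for the probe sets above the floor on all 8 arrays or on all 4 exosome arrays, where few lists could be tested. By fry the cytokine, histone and immediate early lists turned from up to down (mean shifts against the other genes of 0.081, -0.29 and -0.020). Without cell replicate 1 or cell replicate 2, 13 lists passed.

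Exosome-only probe sets were 117 and became 50 with the 99th percentile floor and 388 and 375 within batch 1 and batch 2, where fewer arrays must agree. Leaving out 1 array gave 118 to 165. The background difference of 4.89 on the log2 scale became 0.30 with hybridisation control scaling. The difference of the middle 18S probe set of 6.13 became 1.54 with hybridisation control scaling and 2.62 with poly-A scaling.

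With hybridisation control scaling, Cox8c turned to -0.43, Eif2ak2 to -1.71, Cd151 to -0.92, Zfp934 to -0.35, Zap70 to -0.28, Hnrnpab to -2.40, AY036118 to -2.02 and Gm6958 to -1.24. With poly-A scaling, Eif2ak2 turned to -0.64, Hnrnpab to -1.33, AY036118 to -0.96 and Gm6958 to -0.17. Zscan26 turned to 0.21 with signals set to the floor, and Rps29 to 0.016 with scaling to the detected set. Of all comparisons of named probe sets under an alternative, 2052 kept direction and side of the threshold, 13 lost their call and 14 reversed.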

Other observations

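Among genes with a single symbol, those with the highest exosome signal were listed after the data were seen. Mtm1, a lipid phosphatase, read 10746 ± 2458 in exosomes and 163 ± 19.1 in cells (SD, n = 4), and its 2 other tested probe sets were also higher. Shmt1, which makes glycine from serine, read 6958 ± 1157 and 144 ± 21.5 (SD, n = 4), but 2 of its 3 other probe sets went the other way. Both differences were positive under the deposited and the 5 other scalings (limma, adjusted p = 2.79e-07 and 3.48e-07 with the deposited scaling), but that of Shmt1 did not pass with arrays scaled to the poly-A controls (limma, adjusted p = 0.058). Hnrnpab, AY036118 and Gm6958 were higher with the deposited scaling, though 5 of 6 other probe sets of Hnrnpab went the other way, and their differences turned negative with arrays scaled to the hybridisation or the poly-A controls.

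Probe sets with the suffix _x_at, one of those for probes that can match several transcripts, made up 25.6% of the 640 above the floor on all exosome arrays. They made up 5.42% of all probe sets and 34.0% of the 426 above the floor on all arrays of both groups. Other such suffixes were not counted. The 10 brightest probe sets held 6.45% ± 0.539 of the summed signal on exosome arrays and 1.25% ± 0.0501 on cell arrays (SD, n = 4; exact permutation test, p = 0.029).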
